A study of Rattus norvegicus with 6 samples.

How the data were processed

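Total RNA of common carotid arteries from adult male Sprague-Dawley rats weighing 250 to 300 g was used, per the labels. The rats were anaesthetised with 50 mg/kg phenobarbital, a 2F balloon catheter damaged the lining of the right common carotid artery in the injured group, and arteries were taken after 2 weeks, per the labels. The control arteries are called sham in some of the labels and uninjured or normal in others, so whether these rats had an operation is not settled here. RNA was labelled with Cy3 by a one-colour kit and each sample was hybridised to 1 array, per the labels. The labels number the samples 1 to 3 in each group and do not say that each artery came from a different animal, so the p-values measure the spread between these samples.

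The array files hold spot intensity values deposited as the scanner software wrote them. They were made with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed intensity of a spot is background-subtracted and detrended within its array, with low values replaced by a positive surrogate, and is not scaled between arrays, per the file headers. The files also hold flags of 0 or 1 for spots well above background, saturated or outlying, set by the same software per the file headers. A further deposited table holds log2 values that the authors normalized between arrays by a method not given in the sources used here. Its 6 columns have nearly the same distribution (medians of 4.78 to 4.79), and each correlates with log2 intensities of its own array at 0.989 to 0.999. It was used only as an alternative, its direction and scale being those of the arrays.

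Values were log2 of the processed intensity, averaged over the spots of a probe after spots with outlier flags were left out, minus the 75th percentile of each array over all non-control probes. The files have no mean spot signal, so the alternative background correction (normexp with an offset of 50), planned on mean signals, was run on median spot and background signals. No spot was saturated, so leaving out saturated probes changes nothing and was not run separately. Control probes were left out. A probe was tested when it was well above background on at least 3 of the 6 arrays, whatever their group, which kept 24718 of 38321 probes. Injured and sham arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg over all tested probes. A probe was called at an adjusted p under 0.05. An exact permutation of 3 against 3 arrays cannot give a p under 0.1. For arrays the number per group limits the precision.

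Probe names came from the array files. Of 62 probes named by an accession, 39 matched a transcript of the GRCr8 annotation after versions were removed on both sides. They stand for 38 protein-coding genes, of which 29 were tested. For Ldha, which had 2 tested probes, the probe with the higher mean was used. The other 37277 probes with the maker's ID stay unnamed, and their coordinates and class were not used here. Spots per probe numbered 30 for the reference genes, 10 for catalogue probes and 3 for ultraconserved elements. A gene the text names was to be among the largest changes past the threshold, and if none passed, the 5 with the lowest unadjusted p were to be given as missing it. That rule, the gene lists, the design and most alternatives were fixed before the data were examined. The same rule was applied to ultraconserved elements in place of lncRNAs after the probe names were seen. Of 558 list members, 3 were measured, so set tests were not run, and neither were their alternatives.

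The files put the 6 arrays on 3 slides, taking arrays of a shared scan as 1 slide. Slide 1 held sham 1 and all injured arrays, slide 2 held sham 2 and slide 3 held sham 3. Sham 2 was scanned on another day than the other 5, so a scan-day block is the same as leaving out sham 2. Alternatives covered 4 other scalings, 3 other filters, outlier spots kept, blocks for slide, scan day and replicate number, array weights, a trended and robust eBayes, other thresholds, the authors' values, and each array left out in turn. Added after seeing the data were normexp on median signals, the fit without sham 3 and injured 1, the first principal component as a covariate, and the count of probes whose groups lie at least 2-fold apart.

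The test was run on simulated data for 24473 probes with 200 changed, 50 at each fold size. With the spread of the labelled groups it recovered 0% at each of 2, 4, 8 and 16-fold. With the spread left once the first principal component is taken out it recovered 6%, 72%, 100% and 98% of these. With the component present and fitted as a covariate it recovered 2%, 62%, 98% and 100%, and 17 of 148 calls were false.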

Results

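Gene expression was measured in rat carotid arteries 14 days after balloon injury and in sham arteries, with 3 arrays per group and 1 array per sample. In this model an inflated catheter is drawn through the common carotid artery to strip its inner lining, after which smooth muscle cells of the wall build a new inner layer. The arrays carry probes for long non-coding RNAs and mRNAs, and the comparison asks which of these transcripts differ between injured and sham arteries. Each array held 41623 spots of 38321 probes. The share of probes well above background was 59.5%, 63.2% and 51.5% on sham arrays 1, 2 and 3, and 57.0%, 70.1% and 67.5% on injured arrays 1, 2 and 3. Sham 3 was the dimmest array, with a 75th percentile signal of 89.5 intensity units against 214 to 284 on the other 5. Most probes (37277 of 38321) carry only the array maker's ID, which the tables used here do not pair with a gene or a transcript class. Names could be given to 29 tested protein-coding genes and to probes of ultraconserved elements, and the lncRNA class and lncRNA to mRNA pairs were not analysed here.

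Of the named protein-coding genes, none passed the test between injured and sham arteries. The 5 with the lowest unadjusted p, which all miss the threshold, were Trim2, Slc28a2, Odf2l, Pdcd10 and Cse1l. Trim2, a ubiquitin ligase, averaged 1.31 ± 0.09 (SD, n = 3) in sham and -0.51 ± 1.04 (SD, n = 3) in injured arteries, in log2 units relative to each array's 75th percentile. Its log2 fold change was -1.82 ± 0.64 (SE; limma adjusted p = 0.599), and the 3 injured values lay below the 3 sham values. Slc28a2, a nucleoside transporter, averaged 0.90 ± 0.37 in sham and 2.47 ± 0.86 in injured arteries (SD, n = 3 each). Its log2 fold change was 1.57 ± 0.60 (SE; limma adjusted p = 0.599), with all 3 injured values above the sham values. Odf2l had a log2 fold change of -2.0 ± 0.87 (SE), but it was well above background on only 1 injured array, and the value was -0.74 with normexp background correction. Pdcd10, a gene mutated in cerebral cavernous malformations, had a log2 fold change of -1.55 ± 0.80 (SE). Cse1l, a nuclear export receptor, had a log2 fold change of -1.35 ± 0.74 (SE). The injured and sham values of Odf2l, Pdcd10 and Cse1l overlapped because injured 1 lay within the range of the sham arrays. Leaving out 1 array gave -2.38 to -1.13 for Pdcd10 and -2.04 (without injured 1) to -0.88 (without injured 2) for Cse1l. With the first principal component as a covariate, a setting added after seeing the data, the values were -1.12 for Odf2l, -0.71 for Pdcd10 and -0.57 for Cse1l. Over the 29 genes, 24 fold changes were negative and 5 positive. The number of negative ones was 27 with median scaling and 19 with no scaling. In limma 0 of the 29 passed, also when adjusted over these genes alone (lowest adjusted p = 0.483), and 2 had an unadjusted p under 0.05. All 5 genes passed only with array weights or without both sham 3 and injured 1, the arrays least like their group, a setting also added after seeing the data. Compared within the slide that held sham 1 and all 3 injured arrays, the log2 fold changes of Trim2 and Slc28a2 were -1.91 and 1.90, with a single sham array and so no spread on the sham side.

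Among the reference genes, Actb, Hsp90ab1 and Rpl13a differed widely between arrays of the same group. Actb, the cytoskeletal beta-actin, measured 4.62, 4.62 and 1.31 on sham arrays 1, 2 and 3, and 4.40, -0.24 and -0.06 on injured arrays 1, 2 and 3. Hsp90ab1, a chaperone, measured 4.11, 4.08 and 2.30 in sham and 4.19, 0.65 and 0.54 in injured arteries. Rpl13a, a protein of the large ribosomal subunit, measured 7.32, 7.28 and 5.43 in sham and 7.63, 4.61 and 4.59 in injured arteries. For all 3 of these genes, sham 3, injured 2 and injured 3 were low and injured 1 matched sham 1 and sham 2. Their log2 fold changes between the groups were -2.15 ± 1.56 for Actb, -1.71 ± 1.15 for Hsp90ab1 and -1.06 ± 1.03 for Rpl13a (SE), and none passed the limma test with all arrays weighted alike. Leaving out 1 array gave -3.66 to -1.34 for Actb, -2.90 to -1.08 for Hsp90ab1 and -2.07 to -0.55 for Rpl13a. With the first principal component as a covariate the values were -0.24 for Actb, -0.35 for Hsp90ab1 and 0.15 for Rpl13a, and none passed. With array weights, or without both sham 3 and injured 1, these 3 genes and B2m passed. B2m, the light chain of class I histocompatibility molecules, had a log2 fold change of -0.65 ± 0.57 (SE). Hprt1, a purine salvage enzyme, had -0.52 ± 0.49, and Gusb, a lysosomal glucuronidase, had 0.11 ± 0.46 (SE). Leaving out 1 array gave -1.13 to -0.33 for B2m, -0.76 to -0.21 for Hprt1 and -0.03 to 0.34 for Gusb. Other scalings gave -0.92 to -0.37 for B2m, -0.79 to -0.24 for Hprt1 and -0.17 to 0.39 for Gusb, and the covariate gave -0.21 for B2m. Within the shared slide, where sham 1 is the single sham array, Hprt1 had -0.043. Among glycolytic enzymes, Ldha measured 6.84, 6.82 and 6.63 in sham and 8.25, 6.23 and 8.24 in injured arteries. Pgk1 measured 6.20, 6.27 and 6.24 in sham and 7.28, 5.17 and 7.04 in injured arteries. The sham values of Pgk1 thus had an SD of 0.03 and the injured values an SD of 1.16. A second probe of Ldha had a log2 fold change of -1.42 ± 1.60 (SE) against 0.81 ± 0.68 for the first, and neither sign is established. Leaving out 1 array gave 0.47 to 1.48 for the first probe and -3.15 to -0.27 for the second. With the covariate the values were 1.14 and 0.51, and with array weights 0.49 and -3.79, where the second passed. These 10 reference genes were grouped and named after their values were seen.

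**Figure D1:**
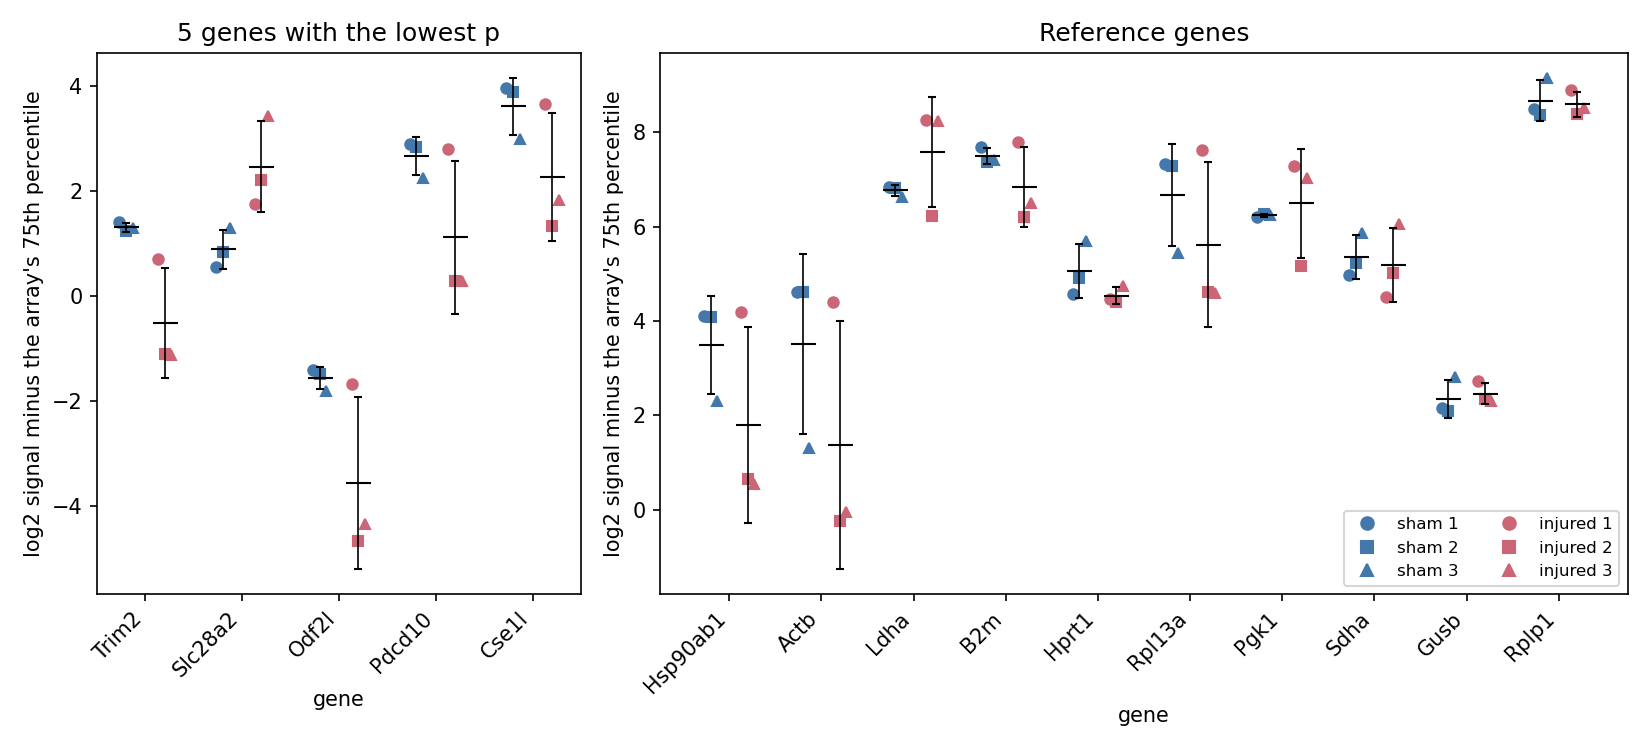
Log2 signal minus each array's 75th percentile (vertical axis) for the 5 named genes with the lowest p and for 10 reference genes, with 1 point per array, blue for sham and red for injured, and black bars for the group mean ± SD (n = 3). Actb, Hsp90ab1 and Rpl13a were low on sham 3, injured 2 and injured 3, and the Actb points span -0.24 to 4.62.

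Of the 27 gene lists fixed in advance, which covered smooth muscle, matrix, proliferation, inflammation and other cell types, 3 had a member that could be measured under a gene name. Each of the 3 had 1 tested gene, and none of these genes was called. Fgf2, the basic fibroblast growth factor, averaged -2.80 ± 0.02 in sham and -2.87 ± 0.79 in injured arteries (SD, n = 3 each). Its log2 fold change was -0.07 ± 0.55 (SE; limma adjusted p = 0.939), with a 95% interval of -1.41 to 1.26. Sdha, a subunit of respiratory complex II, had a log2 fold change of -0.17 ± 0.59 (SE), and Rplp1, a ribosomal stalk protein, one of -0.07 ± 0.47 (SE). Their signs and that of Fgf2 turned to positive with no scaling between arrays, so no direction is given. No list held 3 tested genes, the minimum set for a test, and markers of other cell types could not be used to describe the makeup of the arteries.

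Ultraconserved elements are stretches of the genome identical between human, rat and mouse, some of which are transcribed. The array holds a probe for each strand of 481 such elements, and 311 of the 962 probes were bright enough to test. The probe of the plus strand of element uc.226 was lower on each injured array, at -3.44, -3.97 and -3.54 against -1.37, -1.38 and -1.41 in sham arteries. Its log2 fold change was -2.27 ± 0.43 (SE; limma adjusted p = 0.599), which misses the threshold although the groups lay 2.04 log2 units apart. The next 4 by unadjusted p had positive fold changes, 2.12 ± 0.62 for uc.436-, 2.69 ± 1.01 for uc.464+, 1.39 ± 0.53 for uc.256+ and 2.02 ± 0.78 for uc.266+ (SE). Of these, uc.436- and uc.256+ had all injured values above all sham values, and both were well above background on only 1 sham array. With normexp background correction, whose offset damps differences between dim probes, the fold changes were -0.94 for uc.226+, 0.58 for uc.436-, 1.53 for uc.464+, 0.25 for uc.256+ and 0.78 for uc.266+. All 5 passed with array weights and without both sham 3 and injured 1. The log2 fold change of uc.464+ was 1.78 without injured 2 and 1.66 with the first principal component as a covariate. That of uc.266+ was 0.76 within the shared slide, where sham 1 is the single sham array. Over all 311 probes, 242 fold changes were positive and 69 negative, and 213 to 253 were positive under the other scalings and background corrections. Of all 24718 tested probes, 12928 were positive and 11790 negative. These counts rest on group means and do not show a rise on each injured array. The median over all probes was 0.21 with no filter on dim probes and -0.08 for probes above background on all 6 arrays. Whether dim signals or the filter shape the balance of the ultraconserved elements was not tested. Of 306 probes measured on every array, 18 had all injured values above all sham values and 8 had them below. In limma 0 of the 311 passed, with 9 at an unadjusted p under 0.05 against 15.6 at the nominal rate, which is no measure of chance here. The number of ultraconserved-element probes well above background was 222, 286 and 256 on sham arrays 1, 2 and 3, and 209, 440 and 415 on injured arrays 1, 2 and 3.

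**Figure D2:**
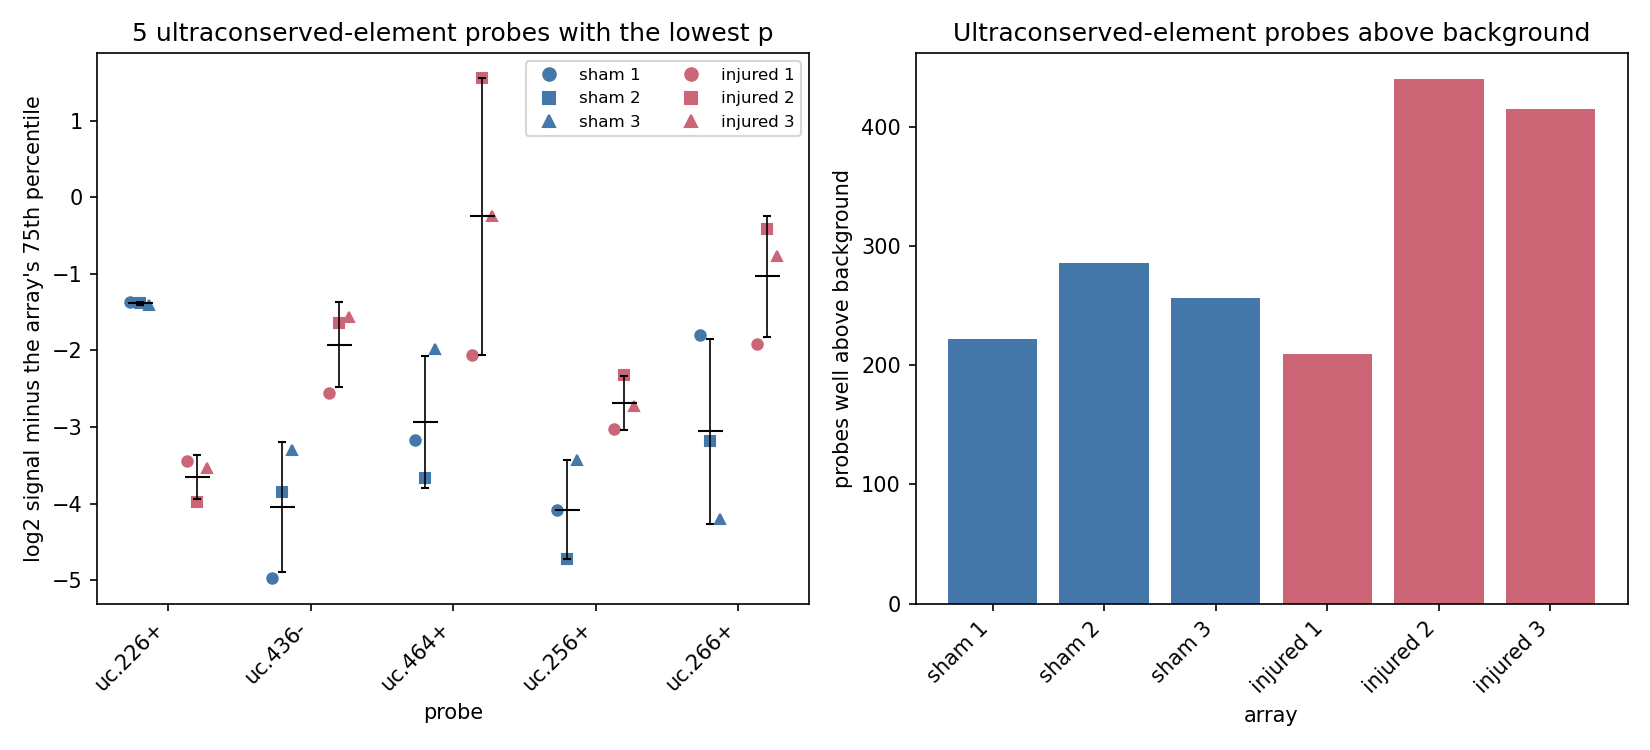
Left, log2 signal minus each array's 75th percentile for the 5 ultraconserved-element probes with the lowest p, with 1 point per array and bars for the group mean ± SD (n = 3). Right, the number of such probes well above background on each array, which was 440 on injured 2 and 415 on injured 3 against 209 on injured 1.

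Over all 24718 tested probes, limma called 0 at an adjusted p under 0.05, with a lowest adjusted p of 0.599. At an unadjusted p under 0.05 there were 1094 probes (590 higher and 504 lower in injured arteries), against 1236 at the nominal rate. That rate is no measure of chance here, since most of the variance lies on 1 component shared by the probes. Of the 9 other splits of the 6 arrays into 3 and 3, the split of injured 1 with sham 1 and sham 2 gave 16402 such probes. The other 8 splits gave 1 to 334. Leaving out 1 array moved the count of the labelled groups to 484, 268 and 1460 without sham 1, 2 and 3, and to 10982, 308 and 326 without injured 1, 2 and 3. With the first principal component as a covariate it was 4455. The median SE of a log2 fold change was 0.78. In simulated data with the measured spread within groups, 0% of probes changed by 16-fold were recovered, so a count of 0 does not show that expression was alike. The 3 injured values lay wholly above or below the 3 sham values for 2876 of 24473 probes measured on every array (11.8%). For 211 of these the gap was at least 2-fold, 133 higher and 78 lower in injured arteries. This count was 59 with normexp background correction and 108 among the 16509 probes well above background on all 6 arrays. The mean share over the 10 splits is 10% by arithmetic, so it is no measure of chance. Putting injured 1 with sham 1 and sham 2 separated 16939 probes, and the other 8 splits separated 122 to 1306. So few splits cannot exclude chance. Among the unnamed probes with the lowest p, ASRNV20016174 was not well above background on any sham array and measured 2.28, 3.50 and 1.29 on the injured arrays. It was at least 92.4-fold higher in injured arteries, taking as the sham level on each array the higher of its own signal and the lowest signal among probes well above background. ASRNV20022365 had a log2 fold change of 5.87 ± 0.60 (SE), with injured values of 2.77, 3.81 and 4.44 against -2.36, -2.53 and -1.70 in sham. ASRNV20018013 had a log2 fold change of -3.51 ± 0.51 (SE), with sham values of 0.15, 0.28 and 0.29. ASRNV20005095 was not well above background on any injured array and was at least 19.1-fold higher in sham arteries by the same bound. With normexp background correction the log2 fold changes were 3.96 for ASRNV20016174, 4.70 for ASRNV20022365, -1.88 for ASRNV20018013 and -1.96 for ASRNV20005095, so both bounds hold only for the processed signal. None of the 4 passed the adjusted threshold (limma adjusted p = 0.599 for each). All 4 passed with array weights and, in settings added after seeing the data, without both sham 3 and injured 1 and with the first principal component as a covariate. ASRNV20016174 and ASRNV20022365 also passed with the replicate block.

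The groups did not set the main order of the arrays. Injured 1 correlated with sham 1 at r = 0.975 across probes, and with injured 2 and injured 3 at 0.594 and 0.604. Sham 3 correlated with injured 2 and injured 3 at 0.892 and 0.897, and with sham 1 at 0.744. The first principal component held 84.7% of the variance, with scores of 0.47, 0.30 and -0.20 for sham arrays 1, 2 and 3 and 0.42, -0.49 and -0.49 for injured arrays 1, 2 and 3. The second held 8.7%, with scores of -0.15, 0.36 and 0.73 for the sham arrays and -0.38, -0.30 and -0.26 for the injured arrays. All sham scores lay above all injured scores. Slide 1 also lay apart from slides 2 and 3, so group and slide cannot be told apart there. Probes are not independent replicates, so these correlations describe the arrays only. With the slide as a fixed block only sham 1 stands against the injured arrays, so the sham side has no replicate, and the 0 calls of limma there (177 probes at an unadjusted p under 0.05) say nothing about the groups. Limma with array weights, which gave little weight to sham 3 and injured 1, called 20225 probes. The fit without both arrays, chosen after seeing the data, called 18151.

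**Figure D3:**
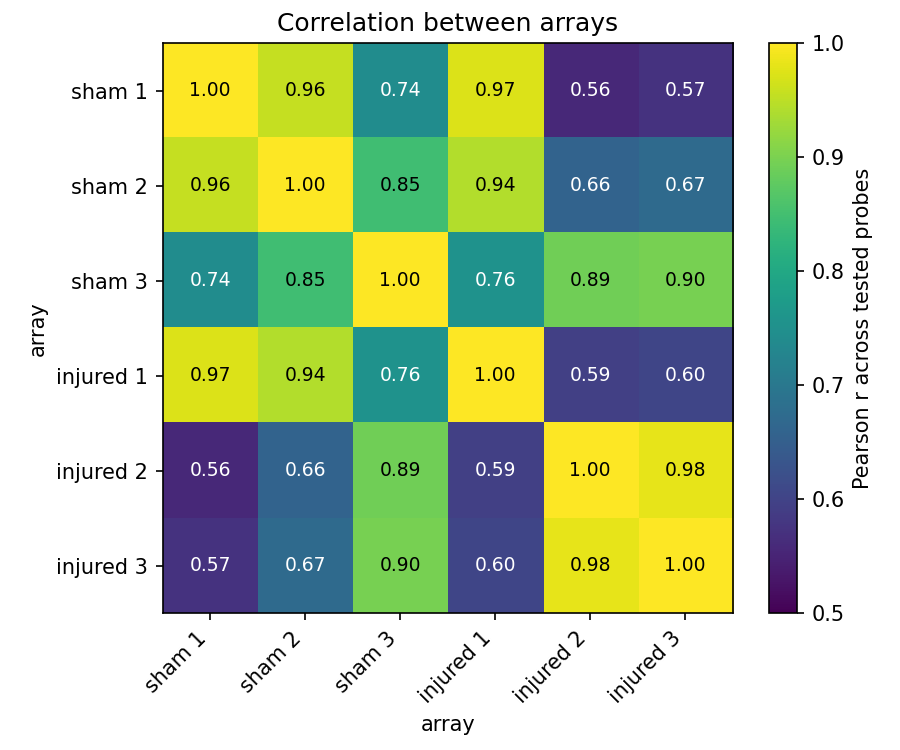
Pearson correlation of log2 signals across tested probes for each pair of the 6 arrays, with array names on both axes and colour for r. Injured 1 correlates at 0.975 with sham 1, and sham 3 at 0.897 with injured 3.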

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

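Control spots, which the comparison leaves out, gave a signal in injured arteries above every sham artery for 9 of 60 control probes. For 2 of these over 50% of spots were also well above background on each injured array and on no sham array. Control probe ETG10_13482 had log2 intensities of 2.36, 1.81 and 1.33 on the sham arrays and 4.67, 6.58 and 3.92 on the injured arrays, a difference of 3.22. Of its 10 spots, 10%, 0% and 0% were well above background on sham arrays 1, 2 and 3, so the size of this difference is not exact. Control probe DCP_22_0 had 3.85, 3.80 and 2.33 on the sham and 4.49, 4.15 and 4.45 on the injured arrays, a difference of 1.04. It has only 2 spots, and 50% of them were well above background on sham 1 and on sham 2, so it was not absent there. Its lowest value came from sham 3, the dimmest array, which widens the difference. The rule took an unscaled signal, and neither difference was tested. Outside the rule, some control probes were bright on injured 2 and injured 3 only. Control probe (+)eQC-39 had log2 intensities of 4.79 and 4.84 there, against 1.70 to 2.05 on the sham arrays and 1.71 on injured 1. Others did not differ in this way, such as (-)3xSLv1 with 1.35 and 1.71 there against 1.29 to 1.76 elsewhere. The cause was not tested, and control probes were not used to weigh the order of the arrays.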

How the results depend on the processing

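Added after seeing the data were normexp on median signals, the fit without both sham 3 and injured 1, and the first principal component as a covariate. The counts of called probes were 0 among all tested probes, among the 30 tested probes of named protein-coding genes and among ultraconserved elements. They were also 0 under the other backgrounds, scalings, filters, slide and scan-day blocks, trended eBayes, thresholds, the authors' values and each array left out in turn (0 to 0). Of the named genes, the authors' values held only the 10 reference genes. These zeros show no robustness, since 0% of 16-fold changes were recovered in simulated data with the spread of the labelled groups, and the fixed slide block leaves 1 sham array. Without injured 1 the lowest limma adjusted p was 0.0524, with 10982 probes at an unadjusted p under 0.05. With array weights (0.14 for sham 3 and 0.058 for injured 1) 20225 probes were called, among them 21 of the 30 named protein-coding probes and 266 ultraconserved-element probes. Without both arrays these counts were 18151, 21 and 243. Both settings set aside the arrays least like their group, which narrows the spread by construction. With the component as a covariate 85 probes and 1 ultraconserved-element probe were called. The replicate block called 3 probes, ASRNV20016174 and ASRNV20022365 among them, with 4835 at an unadjusted p under 0.05. Deviations of arrays with the same number correlated at 0.828, -0.573 and 0.822, and those of sham 3 and injured 2, with unequal numbers, at 0.843. With 3 arrays per group and most variance on 1 component, these values neither show nor exclude that equal numbers pair the arrays. The 211 probes at least 2-fold apart were 59 with normexp and 108 when restricted to probes above background on all arrays, which tests fewer probes; for normexp the cause was not tested.

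The median log2 fold change of all probes was 0.10, and -0.17 with median scaling, 0.29 with the percentile of detected probes and 0.38 with no scaling. The 25 log2 fold changes were computed 437 times under settings other than leaving out an array, of which 415 kept the sign (43 of them past the threshold) and 22 turned; leaving out an array gave 150, of which 141 kept the sign and 9 turned. Those that turned were called in neither setting. Rpl13a turned to 0.15 with the covariate. Fgf2 was 0.12 with the detected-probe percentile, 0.21 with no scaling, 0.36 with array weights and 0.35 without both arrays. Sdha was 0.023, 0.12, 0.37 and 0.43 there, 0.0044 in the authors' values and 0.21 with the slide block. Rplp1 was 0.12, 0.21, 0.048 and 0.020 there, 0.012 with normexp and 0.10 with the slide block. Pgk1 was -0.015 with median scaling, -0.075 with array weights and -0.13 without both arrays. Gusb was -0.17 with median scaling and -0.027 with the scan-day block. With single arrays left out, values ranged from -0.42 to 0.36 for Fgf2, -0.60 to 0.17 for Sdha, -0.23 to 0.17 for Rplp1, -0.14 to 0.92 for Pgk1 and -0.027 to 0.34 for Gusb. The causes were not tested. Saturated spots, set tests and multi-probe lists were not run, since no spot was saturated and no list had 3 tested genes. Dim probes on sham 3 limit what can be seen there.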

Other observations

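The tests in this part were chosen only after the results were seen. Detection of the plus and minus strands of ultraconserved elements was compared on each of the 6 arrays. Fisher's exact test, two-sided and across elements, gave odds ratios of 1.03 to 1.68 and adjusted p-values of 0.157 to 0.894, so no association between strands was shown on any array. The highest odds ratio was on sham 3, with 44 elements detected on both strands where independence gives 34.0 (exact p = 0.0262, adjusted p = 0.157). On injured 2, 213 plus-strand and 227 minus-strand probes were well above background, with both strands detected for 110 of 481 elements where independence gives 100.5. On sham 1 the numbers were 104, 118 and 27, where independence gives 25.5.

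The order of the arrays, with sham 3 beside injured 2 and injured 3 and injured 1 beside sham 1 and sham 2, was weighed against technical explanations. The slide or scan is argued against: sham 1 and injured 2 share a slide and correlate at 0.557, while sham 1 and sham 2 lie on different slides and correlate at 0.956. An exchange of sham 3 and injured 1 could give this order. If so, the labelled grouping would be no better than the other 8 groupings an exchange away from the main one, and it separated 211 probes by at least 2-fold against at most 20 in those 8 (59 against 6 with normexp, 108 against 15 for probes above background on all arrays, and 241 against 81 with no scaling); 9 groupings are too few for this to exclude an exchange. Loss of part of the transcripts, through RNA integrity or priming, may also differ between arrays: the difference between the probes of Ldha was 5.02, 5.13 and 7.26 log2 units in sham and 5.25, 9.0 and 9.84 in injured arteries, a range of 4.83, but 1 transcript does not decide it. A true difference between arteries in injury or tissue makeup stays open and was not tested.

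Probes called once that order is fitted are candidates for an injury response or for a slide difference. Only sham 1 can help to tell these apart, as the single sham array on the slide of the injured arrays. All injured arrays were on slide 1 with sham 1, while sham 2 and sham 3 were on other slides. With the first principal component as a covariate, limma called 85 probes (68 with a positive and 17 with a negative injured minus sham difference in that fit). Without the covariate 65 of these separated the groups, 45 by at least 2-fold. The values of the other 20 overlapped, so the sign of their difference need not hold on each array. For the 65, sham 1 lay on the side of the other sham arrays, although it shares the slide of the injured arrays. A slide difference alone would not give this, but 1 sham array and probes chosen for a group difference do not settle it. Over all 24473 probes measured on every array, 2876 separated the groups, 211 by at least 2-fold. The 85 were chosen for a group difference on the same arrays, so their separation adds no support. One named probe was among them, uc.226+, at -2.17 ± 0.31 (SE; adjusted p = 0.0470, with a range of 8.3e-05 to 0.975 over its settings). Trim2 and Slc28a2 were not, at -1.29 ± 0.39 and 1.14 ± 0.41 (SE; limma adjusted p = 0.191 and 0.229). Of the 10 ways to split the 6 arrays into 3 and 3, the labelled split was the only 1 with a call under this covariate, 85 against 0 at most. The split that puts injured 1 with sham 1 and sham 2 follows the component at r = 0.965, so its 0 calls were to be expected and 8 others remain for comparison. For probes at least 2-fold apart, 2 of the 10 splits reached the labelled count of 211, and the highest of the others had 9693. Without the covariate the labelled count was 0, which any split reaches, so this count says nothing about chance; the highest other, which puts injured 1 with sham 1 and sham 2, called 15294 probes, which points to a structure of the samples. With 10 splits no share under 0.05 is possible. In simulated data 17 of 148 calls under this covariate were false, so some of the 85 may be false too. The simulation drew the spread left around the component separately for each probe, so it does not give the share of the 85 that is false.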
